A study of Mus musculus with 12 samples.

How the data were processed

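Total RNA of 12 samples was measured on the NanoString nCounter system with the Mouse PanCancer Immune panel, per the labels' protocols, which name the PureLink RNA Mini Kit for extraction and the Agilent BioAnalyzer for RNA quality. The authors deposited a table of log2 values for 750 genes, described in the file's name as log2 normalized, and a value table of linear signal for 749 genes. The software, the normalization genes and the treatment of background are not given in the sources used here. The deposited log2 values equal the log2 of the deposited signal for all 749 shared genes, with a largest difference of 5.4e-09. Within each sample, 100% of the signal values were whole multiples of 1 step, within a tolerance of 0.02 counts, so the authors' values are whole probe counts times 1 factor per sample. Dividing by that step recovered the counts, and 1 count was worth between 0.694 and 1.35 units in different samples.

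Groups and replicate numbers came from the labels, and 0 columns of samples outside the series were present. Gene symbols were used as the files give them. In a RefSeq gene table of assembly GRCm38.p6, 736 were current symbols, 8 were synonyms and 6 had no match, and 2 rows (Ptgdr2 and Gpr44) carry the same current gene. No genome build is given in the sources used here, so no coordinates are printed. Probes of closely related families, such as the Klra and H2 genes, were taken at their names, and cross-hybridisation was not tested.

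A background level was set after the data were seen, as the 95th percentile of the recovered counts of 32 T cell and B cell genes in the 2 cell line samples (Gata3 and Tcf7 left out). It was 38.6 counts, times each sample's factor on the log2 scale, where the median of these counts was 16. Blnk, which gave signal in the line, stayed among the 32 genes. The level may thus be set high, and some genes said to be at background may lie above it. Where every sample of the dimmer group was at or below it, the fold is given as "at least", from the brighter group's mean log2 value over the dimmer group's mean of the background levels or, if higher, its own values. No fold is given where both groups were at background. Depth was 368925 to 558445 recovered counts per sample.

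Recovered counts were compared between samples of each group by chi-square over genes with more than 10 combined counts. WT tumours 2 and 3 gave 1.20 per degree of freedom, a small excess over counting noise, the cell line samples 1.64 and other tumour pairs 17.1 or more. The plan had 5 WT tumours against 5 SCID tumours; the reported fits average WT tumours 2 and 3, a choice made after the data were seen, and the fit with both is an alternative.

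SCID and WT tumours were compared with limma 3.58.1 (lmFit and eBayes with default settings, two-sided) on the deposited log2 values of these tumours alone, with no covariate. Both tumour groups were compared with the cell line in 1 fit over all 3 groups, which shares the spread because the line has 2 samples. Genes with a Benjamini-Hochberg adjusted p under 0.05 over 750 genes were called. No pseudocount or filter was applied. Gene lists for cell types and pathways were fixed before the data were examined, and 21 were tested for SCID against WT with fry, Benjamini-Hochberg over the lists, which tests whether a list moves on balance in 1 direction. Camera with a preset correlation of 0.01 and with an estimated one were alternatives. The lists share some genes: Cxcl9, Cxcl10 and Cxcl11, for example, are in the interferon-gamma and the chemokine list. A list of 52 widely expressed genes and one of 19 pan-leukocyte genes were added later. Of the housekeeping list fixed beforehand, 0 genes were in the tables used, so scaling on it was not run. Named genes were, by a rule fixed before the data were examined, the 10 largest rises and 10 largest falls past the threshold of each comparison, and for SCID against WT also the 3 members of each list with the largest absolute change and lineage genes (Cd3e, Cd4, Cd8a, Ms4a1, Ncr1, Foxp3, Gzmb, Ifng and Cd274). Some genes that this rule names are not reported here. H2-D1, H2-Q10, Clu and the genes named in the closing section outside that rule were chosen after their values were seen.

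The fits were tested on simulated data for 750 genes with 100 genes changed by log2 1 and 100 by log2 2. For SCID against WT, 79% of the former and 98% of the latter were recovered, and 3.8% of calls were false. For WT tumours against the line these were 61%, 93% and 4.9%, and for SCID tumours against the line 68%, 95% and 3% of calls. The simulated noise was normal and independent between genes and samples, with as many rises as falls. These rates therefore leave out correlation between genes, probe background, tumours that may share an animal and a mainly one-sided change. Alternatives covered scaling, the value table, filters on low values, a variance trend, replicate and title number blocks, an exact permutation test per gene, each sample left out in turn, values raised to background, and edgeR 4.0.16 (quasi-likelihood) on recovered counts. The last 2, scaling on widely expressed genes, the fit with WT tumours 2 and 3 apart and the fit without WT tumour 1 and SCID tumour 5 were added after seeing the data. With the deposited factors edgeR called 1 gene higher in SCID than in WT tumours and 117 lower, and with TMM factors 10 higher and 58 lower. Single values were compared with exact permutation tests over the 126 splits of 4 against 5. R 4.3.3, Python 3.11.15 and scipy 1.17.1 were used. Confidence intervals cover counting error or, where stated, bootstrap over genes at 95%.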

Results

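Transcripts of immune, stromal and tumour genes were measured with the NanoString nCounter Mouse PanCancer Immune panel, a hybridisation assay that counts barcoded probes without amplification. The 12 RNA samples were 5 subcutaneous mT3-2D tumours from immunocompetent wild-type (WT) hosts, 5 mT3-2D tumours from SCID hosts, and 2 samples of the mT3-2D cell line. The line comes from the KPC mouse model of pancreatic cancer. SCID mice lack mature T and B cells, so the series asked how a tumour grown from the same line differs in expression between the 2 kinds of host. Values for 750 genes were used.

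Whole probe counts recovered from the deposited values summed to between 368925 and 558445 per sample. Clusterin (Clu), a secreted chaperone, took 19.3% to 35.5% of all counts of a sample. Its mean share was 22.5% ± 2.97 (SD, n = 4) in WT tumours and 31.1% ± 3.68 (SD, n = 5) in SCID tumours (exact permutation test, two-sided p = 0.0238, with 0.0079 the smallest p this design allows). In the line the mean share was 30.55% (n = 2). A share of counts also rises when other genes fall, Clu was chosen after its values were seen, and limma did not call it higher in SCID tumours. Genes above the background level numbered 298 and 307 in the cell line samples, 484 to 551 in WT tumours and 416 to 470 in SCID tumours. The probe counts of WT tumours 2 and 3 differed by little more than counting noise, with a chi-square of 1.20 per degree of freedom against 17.1 to 84.5 for the other 19 pairs of tumours within a group. Over all genes this pair differed by more than counting noise (chi-square p = 1.27e-04), while no difference was detected among genes with fewer than 1000 combined counts (1.07 per degree of freedom, chi-square p = 0.112). Their mean was therefore counted as 1 sample, which leaves n = 4 WT tumours, n = 5 SCID tumours and n = 2 cell line samples. The labels do not say which tumours came from separate animals, so p-values measure the spread between these samples only.

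In tumours from SCID hosts, 11 of 15 genes of antigen presentation on MHC class I, 8 of 14 genes of the interferon-gamma response and 6 of 12 lymphocyte-attracting chemokines were lower than in tumours from WT hosts. These 3 lists passed the list test (fry adjusted p = 0.00193, 0.00447 and 0.00283). Camera, a test against the other genes of this immune panel, passed them with its preset correlation (camera adjusted p = 1.22e-05, 0.00103 and 0.0071). With a correlation between genes estimated from the data it did not (camera adjusted p = 0.518 for each). Cxcl9, a chemokine that attracts T cells and is induced by interferon-gamma, was at background in 5 of 5 SCID tumours and at a log2 level of 10.2 ± 1.07 (SD, n = 4) in WT tumours, which makes it at least 29.5-fold lower in SCID tumours (limma adjusted p = 1.01e-04). Cxcl10, a related chemokine, fell by 3.15 on the log2 scale (SE 0.35, adjusted p = 8.83e-04). The classical MHC class I heavy chain H2-K1 fell by 2.58 (SE 0.33, adjusted p = 0.00111), from 10.5 ± 0.77 in WT tumours to 7.95 ± 0.29 in SCID tumours. The tetraspanin Cd9 was the 1 gene that rose, by 0.54 on the log2 scale (SE 0.16, adjusted p = 0.0429).

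Of the 750 genes, 119 differed between SCID and WT tumours at a limma adjusted p under 0.05, 1 higher in SCID tumours (Cd9) and all the others lower. The 10 largest falls were those of Cxcl9, Cxcl10, Chil3, Nlrc5, Tap1, Psmb8, H2-K1, Zbp1, Il2rb and Tap2. Over all genes the median log2 change was -0.33, and over 52 widely expressed genes, chosen after the data were seen, it was -0.08. Scaling every sample to its median over all genes moved the split to 56 higher and 37 lower, and TMM factors on the recovered counts moved it to 10 higher and 58 lower. Scaling on the widely expressed genes gave 1 higher and 120 lower. The call of Cd9 was lost without any 1 of WT tumours 1, 4 and 5, SCID tumours 1 to 5 and the averaged pair (adjusted p between 0.0513 and 0.101).

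Among the 15 measured genes of MHC class I presentation, 11 fell, 0 rose and 4 were not called, with 11 lower when adjusted over the list alone (fry adjusted p = 0.00193; camera adjusted p = 0.518 with an estimated correlation). Nlrc5, the transactivator of MHC class I genes, was at background in SCID tumours and at least 5.23-fold lower (adjusted p = 7.72e-04). The peptide transporter gene Tap1 had a log2 change of -2.82 (SE 0.42), and Psmb8, a subunit of the immunoproteasome, one of -2.79 (SE 0.42), both at adjusted p = 0.00208. Tap2, the partner of Tap1, was at least 3.01-fold lower (adjusted p = 9.18e-04). H2-K1 fell within this list too. The list's fall held when all samples were scaled to their median (fry adjusted p = 0.00718).

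In the interferon-gamma response list, 8 of 14 measured genes fell, 0 rose and 6 were not called, and 10 were lower when adjusted over the list alone (fry adjusted p = 0.00447; camera adjusted p = 0.518 with an estimated correlation). Cxcl9 and Cxcl10 had its largest changes. Cd274, which encodes the checkpoint ligand PD-L1, had a log2 change of -0.96 (SE 0.36, adjusted p = 0.0959). The gene of interferon-gamma itself, Ifng, was at background in all tumours. Of the 12 lymphocyte-attracting chemokines, 6 fell, 0 rose and 6 were not called, with 6 lower when adjusted over the list alone (fry adjusted p = 0.00283; camera adjusted p = 0.518 with an estimated correlation). Ccl5, which attracts T cells, fell by 1.86 (SE 0.45, adjusted p = 0.02). Both lists kept their fall after median scaling (fry adjusted p = 0.0161 and 0.0123).

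Genes of the type I interferon response fell in 6 of 20 cases, with 0 risen, 14 not called and 13 lower when adjusted over the list alone (fry adjusted p = 0.00403; camera adjusted p = 0.518 with an estimated correlation). The nucleic acid sensor Zbp1 changed by -2.33 (SE 0.38, adjusted p = 0.00306), Isg15 by -1.53 (SE 0.34, adjusted p = 0.0149) and Oas2 by -1.51 (SE 0.21, adjusted p = 0.00151). In the MHC class II list, 5 of 9 genes fell, 0 rose and 4 were not called, with 7 lower when adjusted over the list alone (fry adjusted p = 0.0284; camera adjusted p = 0.549 with an estimated correlation). H2-DMb1, which helps load peptides, fell by 1.44 (SE 0.27), the MHC class II transactivator Ciita by 1.43 (SE 0.29) and H2-Eb1 by 1.41 (SE 0.27). After median scaling neither list passed (fry adjusted p = 0.358 for type I interferon and 0.101 for MHC class II). The MHC class II call was also lost without any 1 of WT tumours 4 and 5 and SCID tumours 1 to 4 (fry adjusted p between 0.0528 and 0.0716), and that of Isg15 without WT tumour 5 (0.0512).

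T cell genes were low in tumours of both hosts and lower in SCID hosts. Of 20 measured T cell genes, 12 fell, 0 rose and 8 were not called, with 13 lower when adjusted over the list alone (fry adjusted p = 0.00193; camera adjusted p = 0.518 with an estimated correlation). Cd3e, a chain of the T cell receptor complex, was above background in 1 of 4 WT and 0 of 5 SCID tumours and at least 1.16-fold lower in SCID (adjusted p = 0.00111). Its partner Cd3g was at least 1.46-fold lower (adjusted p = 0.0118), the kinase gene Lck at least 1.30-fold lower (adjusted p = 0.00151) and Cd6 at least 1.16-fold lower (adjusted p = 0.00114). Cd4 and Cd8a passed the threshold (adjusted p = 0.0271 and 0.0345) with both groups at background, so they have no fold. The call of Cd4 was lost without WT tumour 5, SCID tumour 1 or SCID tumour 2 (0.0918, 0.0501 and 0.0645), and that of Cd8a without WT tumour 1, WT tumour 5, SCID tumour 3, SCID tumour 4 or the averaged pair (0.0558, 0.104, 0.0609, 0.067 and 0.0893). In the regulatory T cell list 6 of 8 genes fell, 0 rose and 2 were not called, with 7 lower when adjusted over the list alone (fry adjusted p = 0.00231; camera adjusted p = 0.518 with an estimated correlation). Foxp3, its defining transcription factor, passed (adjusted p = 0.00379) with both groups at background, as did Tnfrsf18, and Il2ra was at least 1.40-fold lower (adjusted p = 0.02). Among 13 immune checkpoint genes 5 fell, 0 rose and 8 were not called, with 8 lower when adjusted over the list alone (fry adjusted p = 0.00231; camera adjusted p = 0.518 with an estimated correlation). Pdcd1, which encodes PD-1, was at least 1.19-fold lower (adjusted p = 0.00332), and Pdcd1lg2, a ligand of PD-1, fell by 1.49 (SE 0.29, adjusted p = 0.00782). None of these 3 lists passed once values were raised to background (fry adjusted p = 0.107 for T cells, 0.111 for regulatory T cells and 0.0662 for checkpoints), nor after median scaling (0.0945, 0.294 and 0.595).

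B cell, NK cell and cytotoxic gene lists did not pass the list test. Of 14 B cell and plasma cell genes 1 fell, 0 rose and 13 were not called, with 1 lower when adjusted over the list alone (fry adjusted p = 0.157), and after median scaling the list was higher in SCID tumours (0.0123). That gene was Cd22 (adjusted p = 0.0211), at background in both groups, as was Ms4a1, and its call was lost without WT tumour 4, WT tumour 5 or SCID tumour 3 (0.0567, 0.0636 and 0.0535). Of the 14 B cell genes, 1 was above background in any WT or SCID sample. Changes of this list in either direction thus rest mostly on counts at background. Among 22 NK cell genes 2 fell, 0 rose and 20 were not called, with 2 lower when adjusted over the list alone (fry adjusted p = 0.157). These 2 were the activating receptor gene Klrk1, at least 1.39-fold lower (adjusted p = 0.0308), and Xcl1, at least 1.80-fold lower (adjusted p = 0.0191; 0.0717 after median scaling and 0.106 with values raised to background). Ncr1, an NK cell receptor gene, was at 5.58 ± 0.56 in WT and 5.54 ± 1.20 in SCID tumours. Of 11 cytotoxic effector genes 1 fell, 0 rose and 10 were not called, with 0 when adjusted over the list alone (fry adjusted p = 0.193), and Gzmb and Gzma were not called (adjusted p = 0.624 and 0.124), though Gzma was without WT tumour 4 (0.0455) and in the replicate block (0.0311). Il2rb, the receptor chain for interleukins 2 and 15 on T and NK cells, fell by 2.27 (SE 0.34, adjusted p = 0.00208). Leaving out WT tumour 5, SCID tumour 2, SCID tumour 3 or the averaged pair ended the call of Klrk1 (adjusted p = 0.0749, 0.0667, 0.0581 and 0.0566). The title number as a random block ended it too (adjusted p = 0.051). The NK cell list passed without WT tumour 4 (fry adjusted p = 0.0109) and the B cell list without SCID tumour 5 (0.0182), in the replicate block (0.0438), in the title series block (0.048) and in the larger title series alone (0.0177). Without both WT tumour 1 and SCID tumour 5 the B cell and cytotoxic lists passed (0.00729 and 0.0466).

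In each myeloid list most genes were not called. Of 18 macrophage and monocyte genes 2 fell, 0 rose and 16 were not called, with 2 lower when adjusted over the list alone (fry adjusted p = 0.0512). Chil3, a chitinase-like protein of alternatively activated macrophages, fell by 3.14 (SE 0.78, adjusted p = 0.0212) and Cd84, a receptor of the SLAM family, by 1.01 (SE 0.19, adjusted p = 0.00644), or by 0.40 after median scaling (adjusted p = 0.15). Arg1 had a log2 change of -1.28 (SE 0.49, adjusted p = 0.1) and was called without WT tumour 1 (adjusted p = 0.0406), without both WT tumour 1 and SCID tumour 5 (0.0365) and in the replicate block with WT tumours 2 and 3 apart (0.00673). Of 11 dendritic cell genes 1 fell (Cd83, by 1.45, SE 0.35, adjusted p = 0.02), 0 rose and 10 were not called, with 4 lower and 1 higher when adjusted over the list alone (fry adjusted p = 0.0399; camera adjusted p = 0.903 with an estimated correlation). Among 19 myeloid-attracting chemokines and inflammatory cytokines 3 fell, 0 rose and 16 were not called, with 4 lower when adjusted over the list alone (fry adjusted p = 0.0323; camera adjusted p = 0.825 with an estimated correlation). Ccl8 fell by 1.58 (SE 0.38, adjusted p = 0.0197) and Tnf by 1.19 (SE 0.30, adjusted p = 0.0251). Of 24 complement genes 3 fell, 0 rose and 21 were not called, with 2 lower when adjusted over the list alone (fry adjusted p = 0.0323; camera adjusted p = 0.903 with an estimated correlation). C3, the central component, fell by 1.55 (SE 0.22, adjusted p = 0.00199). The direction of the dendritic cell, myeloid chemokine and complement lists turned upward after median scaling, without passing the test (fry adjusted p = 0.841, 0.841 and 0.358). These 3 lists did not pass either once values were raised to background (0.0662, 0.0891 and 0.0662) or with camera's preset correlation (camera adjusted p = 0.839, 0.546 and 0.839). Neutrophil genes had 1 fall (Csf3r, by 0.81, SE 0.22, adjusted p = 0.0321), 0 rises and 11 not called of 12, with 1 lower when adjusted over the list alone (fry adjusted p = 0.106). None of 5 mast cell genes was called, nor when adjusted over the list alone (fry adjusted p = 0.157).

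Without WT tumour 5, Chil3, Cd83, Ccl8, Tnf and Csf3r were not called (adjusted p = 0.0718, 0.0635, 0.0636, 0.0822 and 0.0918), and without the averaged pair they were not called either (0.0566, 0.0566, 0.0537, 0.0661 and 0.081). Leaving out WT tumour 4 ended the calls of Chil3, Tnf and Csf3r (0.0512, 0.0666 and 0.079), SCID tumour 2 that of Tnf (0.0601), and SCID tumours 1 or 3 that of Csf3r (0.0653 and 0.0746). The macrophage list passed without WT tumour 1, WT tumour 2 or SCID tumour 5 (fry adjusted p = 0.0459, 0.0465 and 0.0182), and the neutrophil list without WT tumour 1 (0.0145). The macrophage list also passed in the replicate block (0.0362), in the larger title series alone (0.0174) and when scaled on widely expressed genes (0.0388). Without both WT tumour 1 and SCID tumour 5 the macrophage, neutrophil and mast cell lists passed (0.0204, 0.0214 and 0.0468). The dendritic cell, myeloid chemokine and complement lists each lost their call without WT tumour 4, SCID tumours 1, 2 or 3 or the averaged pair, with fry adjusted p between 0.0528 and 0.0879 over these, and the last 2 also without WT tumour 5 (0.0908 and 0.0837). SCID tumour 4 ended the dendritic cell and complement calls too (0.0932 and 0.0676).

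Stromal, epithelial and proliferation genes were not called as groups. None of 11 endothelial genes and none of 12 fibroblast and matrix genes was called, nor when adjusted over each list alone (fry adjusted p = 0.351 and 0.918); after median scaling the fibroblast list was higher in SCID tumours (fry adjusted p = 0.0163). Pecam1, an endothelial adhesion molecule, changed by -0.36 (SE 0.31, adjusted p = 0.469), and Fn1, which encodes fibronectin, by -0.30 (SE 0.20, adjusted p = 0.329). Of 9 epithelial tumour cell genes 1 rose (Cd9), 0 fell and 8 were not called, with 0 when adjusted over the list alone (fry adjusted p = 0.359). Epcam, an epithelial adhesion molecule, varied widely within both groups, at 11.7 ± 1.29 in WT and 10.4 ± 1.68 in SCID tumours, and was called lower only without both WT tumour 1 and SCID tumour 5 (-1.20, adjusted p = 0.0474). None of 6 proliferation genes was called, nor when adjusted over the list alone (fry adjusted p = 0.158), although the list turned higher in SCID tumours after median scaling (0.0213) and passed without WT tumour 4 (0.0415). Genes common to all leukocytes, a list of 19 chosen after the data were seen, included 6 that fell, 0 that rose and 13 not called, with 13 lower when adjusted over the list alone and a median log2 change of -0.82.

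**Figure D1:**
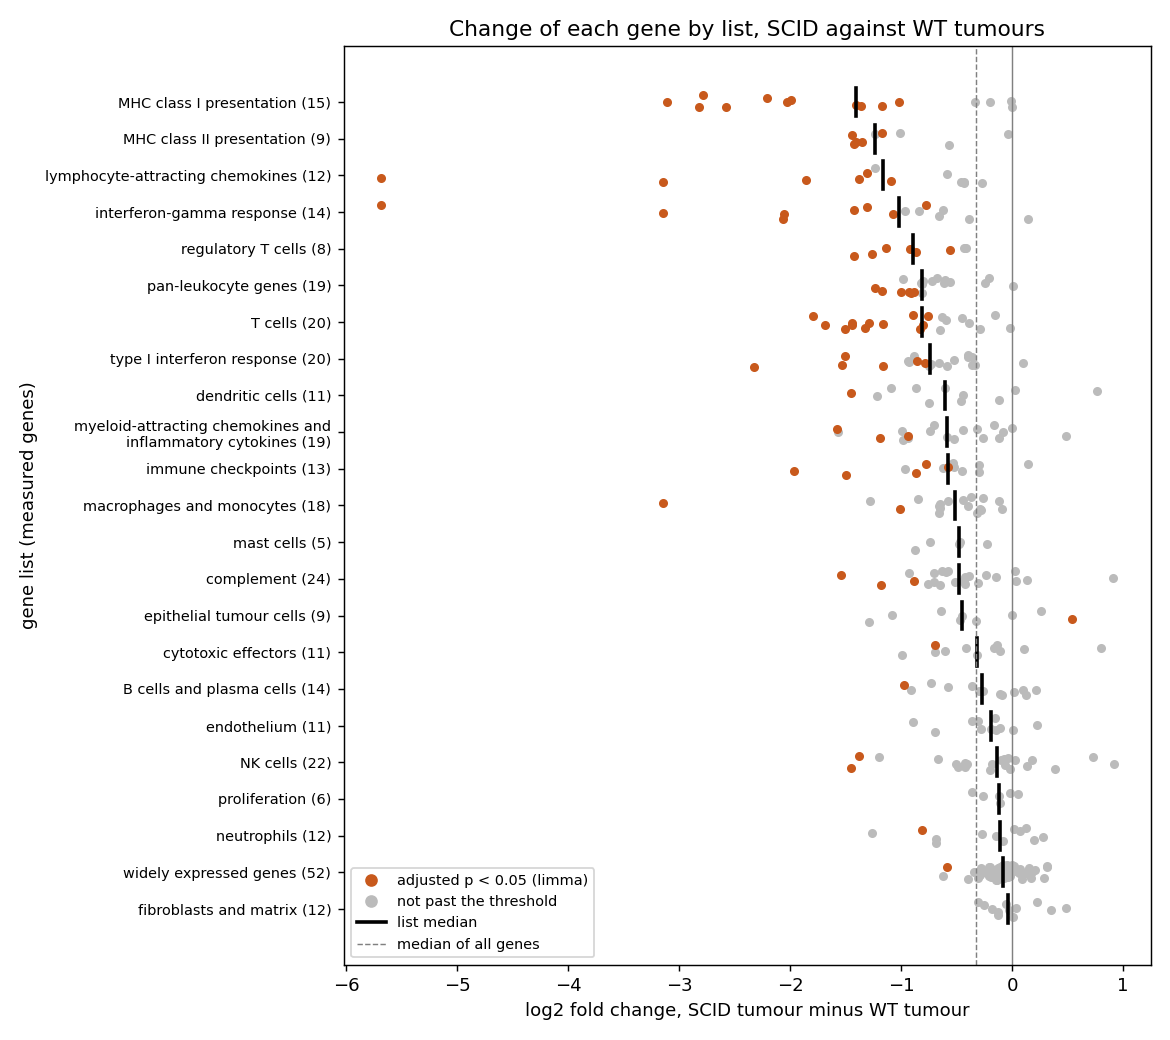
Log2 fold change of each measured gene, SCID minus WT tumours (x axis), by gene list (y axis, with the number of measured genes), where orange points passed an adjusted p of 0.05, black bars are list medians and the dashed line is the median of all genes (-0.33). The 4 lists with the lowest medians were MHC class I, MHC class II, lymphocyte-attracting chemokines and interferon-gamma response, as deposited values give them.

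**Figure D2:**
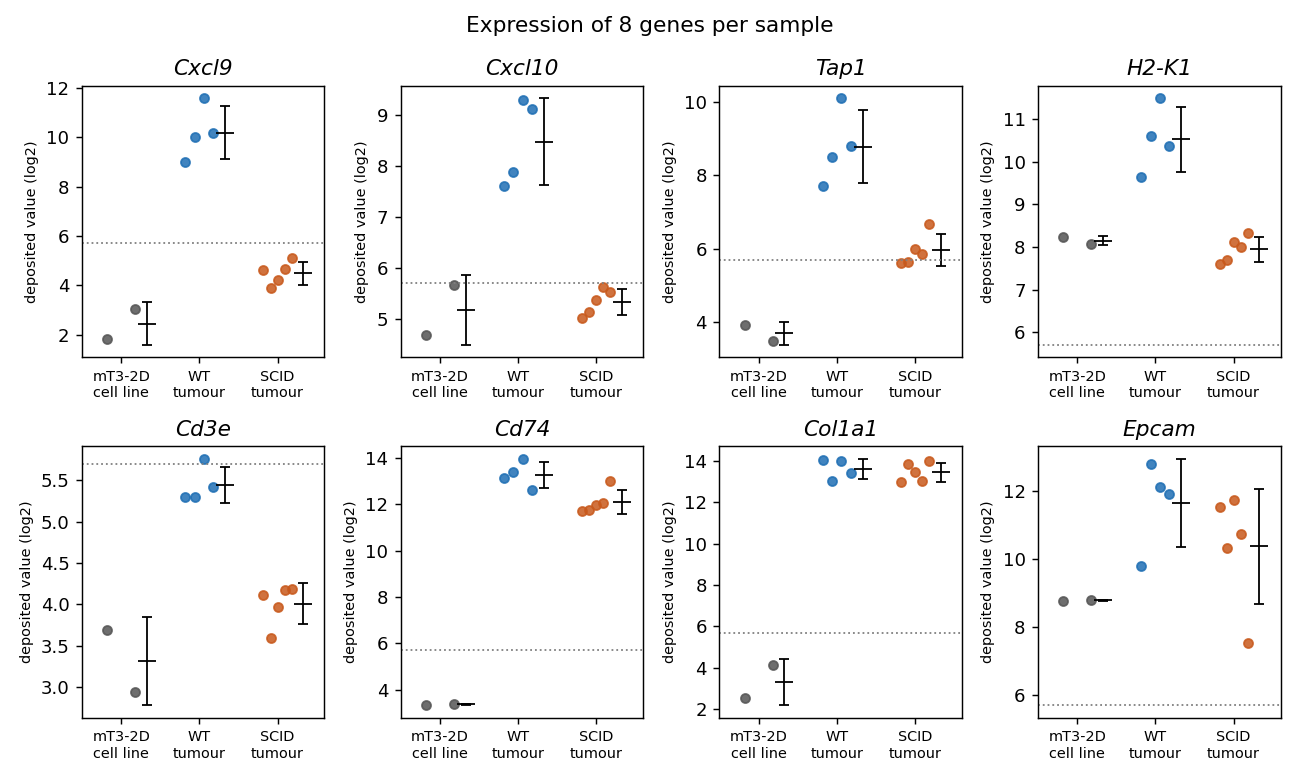
Deposited log2 value (y axis) of 8 genes in each sample of the cell line (n = 2), WT tumours (n = 4, with WT tumours 2 and 3 averaged) and SCID tumours (n = 5), with mean and SD in black and the highest background level of any tumour dotted. Cxcl9 lay below that level in all SCID tumours and above it in all WT tumours, while Col1a1 overlapped between the 2 hosts.

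After median scaling, 15 named genes were no longer called (Cd22, Foxp3, Il2ra, Tnfrsf18, Klrk1, Xcl1, Isg15, Cd84, Cd83, Csf3r, Ccl8, Tnf, C2, Cd4 and Cd8a), with adjusted p between 0.0531 and 0.589. With values raised to background, 17 were no longer called (Cd3e, Cd3g, Lck, Cd6, Cd22, Foxp3, Il2ra, Tnfrsf18, Klrk1, Xcl1, Pdcd1, Csf3r, Tnf, Ccl5, C2, Cd4 and Cd8a), with adjusted p between 0.0585 and 0.484. With the title number as a random block, 5 named genes were no longer called, Klrk1 and Cd9 among them (limma adjusted p = 0.051 and 0.0595). Without WT tumour 5 the count of called genes was 67, and with values raised to background it was 62. In the titles WT tumours 3, 4 and 5 share a number, SCID tumours 1 and 2 share a different one, and SCID tumours 3 and 4 share yet another. The averaged pair was placed under the number of WT tumour 3, although WT tumour 2 carries another. Averaging tumours that share a number left 1 call, Cxcl9, at a log2 change of -5.19 (limma adjusted p = 0.0447). That test set WT tumour 1 and 1 WT mean against SCID tumour 5 and 2 SCID means. With so few values per host it had little power to keep the other calls. The tumours of the larger title number series alone gave 165 calls, the smaller series holding 1 tumour per host.

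Tumours in WT hosts held abundant transcripts of genes known from macrophages, antigen-presenting cells and matrix that were at background in cultured mT3-2D cells. Lyz2, the lysozyme of macrophages and neutrophils, was at 13.0 ± 0.17 in WT tumours (SD, n = 4) and at background in the line (n = 2), at least 290.9-fold higher (limma adjusted p = 7.3e-10). The collagen genes Col1a1 and Col3a1 were at least 463-fold and 320.0-fold higher (adjusted p = 1.55e-08 and 7.6e-08). Cd74, the MHC class II invariant chain, was at least 365-fold higher (adjusted p = 7.5e-09), and C1qb and C1qa of the complement C1q complex at least 59.3-fold and 46.5-fold higher. Ccl20, a chemokine for Ccr6-bearing cells, was lower in WT tumours, by a log2 change of -2.94 (SE 0.42, adjusted p = 8.62e-05), as were the cystine transporter Slc7a11 (-1.80, SE 0.36) and the transferrin receptor Tfrc (-1.75, SE 0.28).

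Between WT tumours and the line, 523 of 750 genes differed, 503 higher and 20 lower in tumours. Apoe, H2-Ab1, Ctss and H2-Aa completed the 10 largest rises, and the other falls among the 10 largest were those of Il5ra, Il1rn, Abcb1a, Tigit, Pparg, Il22ra1 and Masp1. Of the macrophage and monocyte genes 17 of 18 were higher, of endothelial genes 11 of 11, of fibroblast and matrix genes 10 of 12, and of MHC class II genes 8 of 9, with 17, 11, 10 and 8 when adjusted over each list alone and 0 lower in each. In the MHC class I list 11 of 15 were higher and 1 lower (H2-Q10), the same numbers as when adjusted over the list alone. In the T cell list 17 of 20 were higher and 0 lower, with 17 when adjusted over the list alone and 6 of them at background in both groups. Of epithelial genes 4 of 9 were higher and 0 lower, with 2 when adjusted over the list alone. Scaled to the median of all genes the split was 106 higher and 484 lower, and with TMM factors 246 higher and 149 lower. Scaled on the widely expressed genes chosen later, it was 510 higher and 21 lower. The median gene of the line samples (log2 4.04 to 4.12) lay below their background level (4.74 to 4.79). Median scaling against the line thus aligned background counts with the median gene of the tumours. Of the 523 genes, 97 were at background in both groups, where 1 count was worth 0.694 to 0.717 in the line and 1.03 to 1.35 in WT tumours. The calls of Pparg and Il22ra1 were lost without either cell line sample (adjusted p = 0.105 and 0.0718 for Pparg, 0.0968 and 0.0722 for Il22ra1) and that of Masp1 without cell line sample 1 (0.136).

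Col3a1, Col1a1, Lyz2 and Cd74, at background in the line, were higher in SCID tumours too, while their H2-K1 and H2-D1 levels were not distinguished from those of the line. Col3a1 was at least 374-fold higher than in the line (limma adjusted p = 7.47e-08), Col1a1 at least 410-fold (1.63e-08), Lyz2 at least 140-fold (1.53e-09) and Cd74 at least 162-fold (1.63e-08). H2-K1 was at 7.95 ± 0.29 in SCID tumours (SD, n = 5) and 8.15 ± 0.11 in the line (n = 2), a log2 change of -0.20 (SE 0.39, adjusted p = 0.658), and H2-D1 changed by 0.30 (SE 0.36, adjusted p = 0.501). Psmb8 was higher than in the line by 4.90 (SE 0.52, adjusted p = 1.32e-05) and Tap1 by 2.27 (SE 0.51, adjusted p = 0.00318).

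Between SCID tumours and the line 408 genes differed, 387 higher and 21 lower in tumours. C1qb, Apoe, C1qa, H2-Ab1 and the protease gene Ctss were also among the 10 largest rises. Ccl20 had the largest fall, -3.38 (SE 0.41, adjusted p = 3.4e-05), followed by the immediate early gene Fos (-2.14), Slc7a11 (-2.02), Tfrc, Il1rn, Masp1, Blnk, Il5ra, Tigit and Tnfrsf10b. Of macrophage and monocyte genes 16 of 18 were higher, of endothelial genes 10 of 11, of fibroblast and matrix genes 10 of 12 and of MHC class II genes 8 of 9, with 16, 10, 10 and 8 when adjusted over each list alone and 0 lower. In the MHC class I list 8 of 15 were higher and 1 lower, with the same numbers when adjusted over the list alone. In the T cell list 8 of 20 were called higher and 0 lower, as when adjusted over the list alone, against 54.4% of all genes called, and 6 of these 8 were at background in both groups. The median log2 change of that list was 0.58, while 1 count was worth 0.694 to 0.717 in the line and 0.922 to 1.21 in SCID tumours. Median scaling, for which the line's median gene lay below background, gave 101 higher and 481 lower, and TMM factors 202 higher and 124 lower. Scaling on widely expressed genes gave 392 higher and 20 lower. Of the 408 genes, 85 were at background in both groups. Without either cell line sample the calls of Fos (adjusted p = 0.079 and 0.0747) and Il5ra (0.0838 and 0.0766) were lost, as was that of Masp1 without cell line sample 1 (0.0577).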

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

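All explanations weighed below were tested after the results they bear on had been seen. In each of 242 groups of values (a named gene, a list mean or the Clu share, in WT or in SCID tumours) the most distant sample was compared with the range of its group; chance marks about 1 group in 20, or 12.1 here, and 8 were marked.

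WT tumour 1 was the lowest WT sample for Ccl8 (log2 9.78, others 10.8 or above), Il22ra1 (5.13, others 6.27 or above) and Tnf (5.09, others 6.13 or above). SCID tumour 5 was the highest SCID sample for Cd74 (13.0) and the lowest for Pparg (5.77, others 7.17 or above). Il5ra was lowest in SCID tumour 4 (7.27), Nlrc5 in SCID tumour 3 (3.69, below background) and Vcam1 in SCID tumour 2 (6.38).

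Of the 119 genes called between hosts, all but 1 were lower in SCID tumours. The 52 widely expressed genes had a median log2 change of -0.078 (95% bootstrap interval over genes -0.13 to -0.03), against -0.33 for all genes, so the median gene fell relative to them. Whether the deposited scaling set the SCID values too low is not decided by this. The genes behind the deposited factors are not given, and factors set on similar genes would hold widely expressed genes level. Median scaling turned the split to 56 higher and 37 lower, and TMM factors moved the median change of all genes to -0.012. Scaling on the 52 widely expressed genes gave 1 higher and 120 lower, with a median change of all genes of -0.33. How many of the smaller changes are falls thus depends on which genes are taken as level, and stays open. Probe background as the whole reason is argued against by 103 of the 119 genes being above background in at least 1 tumour. With values raised to background 62 calls were left, 98.4% of them lower. That share decides nothing about direction, since raising values shrinks changes and the level itself was lower in SCID tumours. Foxp3, at background in both hosts, then read -0.103. Chance can be excluded for the number of calls only if the 9 tumours are independent samples, which the labels do not say: in 100 of the 126 possible splits, 1 split, the real one, gave 119 calls and the highest other 23, while averaging tumours that share a title number left 1 call.

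Interferon-gamma response and MHC class I genes were lower in SCID tumours, and a smaller share of leukocytes alone would lower them no further than the pan-leukocyte genes. The 29 genes of both lists fell further than the 19 pan-leukocyte genes by -0.78 on the log2 scale (exact permutation test, two-sided p = 0.0159), with changes of -1.51 and -0.73. An MHC haplotype of the host that the probes read less well would bear on genes inside the MHC region. The fall was not confined to these. The 17 list genes outside the region had a median change of -1.07 (95% bootstrap interval over genes -2.06 to -0.66). Their falls had been seen beforehand, so this value is no test of the haplotype. The 12 list genes inside the region were 7 H2 genes with Tap1, Tap2, Tapbp, Psmb8 and Psmb9. For them a haplotype effect cannot be told apart from the host. H2-Ea-ps, a transcript of some haplotypes, was above background in 0 SCID and 0 WT tumours, and other haplotypes lack it too. The difference between the hosts stays open as the biological explanation and was not tested; Ifng was at background in both.

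WT tumours 2 and 3 gave nearly the same counts. Their chi-square per degree of freedom was 1.20, below the 1.64 of the 2 cell line samples and far below the 17.1 of the closest other tumour pair, which is consistent with 1 RNA measured in both. Their titles carry numbers of different series, and whether a label or a tube was repeated stays open. No biological explanation was tested.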

How the results depend on the processing

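Between SCID and WT tumours, the 119 calls became 46 with genes below the median of mean values left out (45 lower), 70 with at least a 2-fold change (0 higher, 70 lower), 1 with tumours sharing a title number averaged (0 higher, 1 lower), 0 in the exact permutation test per gene (0 higher, 0 lower), whose smallest p is 0.0079 and where limma had 238 genes at an unadjusted p under 0.05. Alternatives chosen after seeing the data gave 62 with values raised to background (61 lower), 68 with edgeR and TMM factors (10 higher, 58 lower), and 195 without WT tumour 1 and SCID tumour 5 (6 higher, 189 lower). Median scaling, which moved the median change of all genes from -0.33 to 0.28, gave 56 higher and 37 lower. Scaling on widely expressed genes gave 121 calls (1 higher, 120 lower). The genes called higher numbered 2 with all 3 groups in the fit, 2 with the title number series as a block, 3 in the larger series alone, 0 with the title number as a random block and 2 with WT tumours 2 and 3 apart (157 calls in all). With 1 tumour left out, calls ranged from 67 (without WT tumour 5) to 158 (without SCID tumour 5), with 0 to 3 higher and 67 to 156 lower. The replicate block, with WT tumours 2 and 3 apart, gave 161 calls; same-numbered tumours did not deviate together (r from -0.41 to 0.24), so the numbers do not pair them. Lists turned direction after median scaling for B cells (adjusted p = 0.0123), fibroblasts (0.0163), proliferation (0.0213) and, without passing, NK cells (0.121), cytotoxic effectors (0.155), macrophages, dendritic cells, mast cells and myeloid chemokines (0.841 each), neutrophils (0.107), complement (0.358), endothelium (0.101) and epithelium (0.372). In the B cell list, 1 of 14 genes was above background in any WT or SCID sample. Camera, which compares a list with the other genes, turned fibroblasts with its preset correlation (0.0118; 0.518 with an estimated one) and, without passing, B cells (0.533; 0.825), NK cells (0.151; 0.549), cytotoxic effectors (0.546; 0.825), neutrophils (0.353; 0.549), endothelium and epithelium (0.391; 0.825 for both) and proliferation (0.391; 0.549). The fibroblast list also turned without passing in the replicate block (0.944), the series block with WT tumours 2 and 3 apart (0.908), with them apart alone (0.894) and without WT tumour 1 or 5 or SCID tumour 1 or 3 (0.436 to 0.952 over all left-out tumours). Genes not called in either setting turned too: after median scaling Tpsab1 (log2 change 0.13), Pecam1 (0.25), Fn1 (0.31), Cdk1 (0.25), Cdkn1a (0.35), Birc5 (0.49), Ms4a1 (0.33), Ncr1 (0.57), Gzmb (0.29) and Ifng (0.19), and with TMM factors Pecam1 (0.001), Fn1 (0.012), Cdkn1a (0.054), Birc5 (0.21), Ms4a1 (0.036) and Ncr1 (0.53). Birc5 turned without WT tumour 1 and SCID tumour 5 (0.046), Ncr1 and Gzmb with tumours sharing a number averaged (0.25 and 0.079), and Ncr1 with values raised to background (0.17) and edgeR with deposited factors (0.22). With 1 tumour left out, Birc5 ranged from -0.38 to 0.029, Ncr1 from -0.38 to 0.30 and Gzmb from -0.61 to 0.075. With an estimated correlation, or tumours sharing a number averaged, none of the 11 called lists passed. Camera's preset correlation kept MHC class I (camera adjusted p = 1.22e-05), T cells (1.93e-04), interferon-gamma (0.00103), lymphocyte-attracting chemokines (0.0071) and MHC class II (0.0126). It also kept regulatory T cells and type I interferon (0.00359 each) and checkpoints (0.0392), but not dendritic cells, myeloid chemokines or complement. Against the line, leaving out genes below the median gave 254 calls (237 higher) for WT and 214 (197 higher) for SCID tumours. Median scaling gave 106 higher and 484 lower for WT and 101 and 481 for SCID, and TMM factors 246 and 149 for WT and 202 and 124 for SCID. Scaling on widely expressed genes gave 510 higher and 21 lower for WT and 392 and 20 for SCID. At 2-fold, 12 and 13 were lower, and with a replicate block on numbers 1 and 2 10 were lower in WT tumours. With 1 sample left out, the lone line sample being assumed to vary like the tumours, calls ranged from 421 to 533 for WT (407 to 510 higher, 12 to 23 lower) and from 283 to 413 for SCID (273 to 393 higher, 10 to 21 lower), the lowest totals being those without either cell line sample for WT and without sample 1 for SCID. The cause was not tested, except that filters and left-out samples test fewer genes or samples and that scaling shifts every gene alike. Counting noise limits the 173 genes at background in both hosts, of which 16 were called. Scaling on the housekeeping list was not run. Of the other alternative values, 368 of lists and 1743 of named genes between hosts had the direction and side of the threshold reported, 61 and 173 no longer passed, and 18 and 55 newly passed.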

Other observations

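Within both hosts the tumours differed in epithelial genes. Epcam, an epithelial adhesion molecule, was at log2 7.55 in SCID tumour 5 and 9.80 in WT tumour 1, against 10.3 to 12.8 in the other tumours. Muc1, a membrane mucin, was at 8.33 and 8.92 in these 2 tumours, and the secreted scavenger protein Dmbt1 at 9.55 and 9.02, against 12.3 to 14.1 in the others. Col3a1 was at 14.6 in SCID tumour 5, above all others, while WT tumour 1 at 13.7 lay within the 12.4 to 13.8 of the remaining tumours. These 2 tumours also stood apart on the second principal component of the 9 tumours (19.4% of the variance, scores of 11.7 and 9.80), while the first (49.5%) separated the hosts. SCID tumour 5 was the only SCID tumour of the smaller title number series, and WT tumour 1 belonged to the larger series. For SCID tumour 5 a difference between the series cannot be told apart from variation between tumours.

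Some probes named for lymphocyte genes gave signal in the cultured tumour cells. Il5ra, an interleukin 5 receptor chain, was at log2 9.62 ± 0.02 (SD, n = 2), Tigit, a receptor of T and NK cells, at 7.54 ± 0.01 and Blnk, an adaptor of B cell receptor signalling, at 6.96 ± 0.01, all above background in 2 of 2 samples. Each was lower than in the line in tumours of both hosts, Blnk by 1.05 in WT tumours (SE 0.29, limma adjusted p = 0.00793) and by 1.62 in SCID tumours (SE 0.28, limma adjusted p = 5.52e-04).

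A hypothesis formed after these values were seen is that the share of epithelial tumour cells against stroma differs between tumours of the same host. A score of the 9 epithelial genes and one of the 23 endothelial and fibroblast genes, both lists complete and each score centred on its host group, were compared over the 9 tumours. Pearson's r was -0.90 (permutation p = 0.0022) and Spearman's rho -0.77 (permutation p = 0.031, both from 100000 permutations within hosts), and without WT tumour 1 and SCID tumour 5 r was -0.72. This does not decide it, since the list holds 5 genes (Epcam, Cdh1, Muc1, Msln and Ceacam1) that had been seen to vary in this way: a score of these alone, 1 of 3 relations computed, gave r = -0.92 and is no test, and one of the other 4 (Egfr, Cd44, Nt5e and Cd9) gave 0.20 (permutation p = 0.61). A change of state of the tumour cells could give the same relation and was not tested.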
